A study of Mus musculus with 8 samples.

How the data were processed

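Whole-blood RNA of mice was isolated, amplified and labelled with biotin by the Affymetrix one-cycle method and hybridised to 1 array per sample, per the labels' protocols. There were 8 arrays, 4 from mice given CoCl2 and 4 controls, grouped by the stress label of each sample. The labels call the controls chamber controls, and they give the treatment text with the CoCl2 samples only. Arrays were processed with GCRMA and Partek, per the submitters' processing notes, whose versions are not given in the sources used here.

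The deposited value table holds a score per probe set and array that is not usable as it stands. Its columns have medians between 268 and 277, because the decimal point of each log2 value was lost and the digits were regrouped, and some values became spreadsheet day numbers. The decimal point was restored from the digits alone. A cell was read with 1 digit before the point (353377 of 360808 cells), with 2 digits (7013), as a day number (405) or as it stood (13). In 1317 cells (0.365%) several readings were possible, and the one nearest to an unambiguous array of the same probe set was taken, without use of the groups. On simulated damage, 99.9% of cells came back within 0.005, and 96.3% of ambiguous ones. Restored values span 1.69 to 16.89. That they are log2 is inferred from this range and from the deposited comparison table, and no header states it. They were not normalized further. The fixed design had assumed log2 values as deposited, so the test stayed as planned and ran on the restored values.

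The authors' comparison table comes from SAM, per the file headers. It holds a score (the difference over its error), a deposited numerator that is a log2 difference of group means, its denominator, a fold change that is a ratio on the linear scale as deposited, and a deposited q-value in percent. Its settings and the arrays that entered it are not given in the sources used here, and its numerators differ from the restored values, so it was made from other values or arrays.

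Of 45101 probe sets, 64 controls with AFFX IDs were left out of the test, and the upper 50% by mean log2 value over all 8 arrays (22518 probe sets, mean of at least 2.90) was tested. limma 3.58.1 in R 4.3.3 was used, with lmFit and eBayes at default settings, CoCl2 minus control, two-sided, Benjamini-Hochberg adjustment and a threshold of 0.05. The fit was tested on simulated arrays with 200 of 22518 probe sets changed between CoCl2 and control. It recovered 2% of those changed by 0.5 on the log2 scale, 36% of those changed by 1, 88% of those raised by 2 and 84% of those lowered by 2, and it called 4 unchanged ones. In the data 45.1% of tested probe sets passed, and the Benjamini-Hochberg adjustment is less strict when more probe sets change. The simulated shares therefore do not give the recovery in these data. Controls were compared by two-sided exact permutation of the arrays.

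The choices above and the alternatives were fixed before the data were examined, apart from the decimal restoration and 4 alternatives added later. The files do not pair probe set IDs with genes. The planned gene-level count, the 24 gene lists, the sex check and the naming of genes are therefore void and not analysed here, and so are their alternatives. The rule for named genes took the largest rises and falls among probe sets past the threshold with no overlap between groups, and 2 IDs per direction are named by it. Alternatives were no filter, a stricter filter, quantile normalization, median centring, a trended robust prior, array weights, a replicate block, each array left out, the authors' table, a count without overlap and limma's treat test. Added after seeing the data were ambiguous cells set to missing, the probe sets of the authors' table, arrays centred on bioB and bioC controls, and a mean over 3 repeat control probe sets.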

Results

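Gene expression in whole blood of mice given cobalt chloride (CoCl2) was compared with that of control mice on one-colour Affymetrix arrays. CoCl2 is a cobalt salt that stabilises hypoxia-inducible factors at normal oxygen, and its use is therefore called chemical hypoxia. The CoCl2 group held 4 arrays and the control group 4 arrays, each from blood drawn from the vena cava. Per the labels, treated mice received 200 ng CoCl2 per 100 ml per day, and blood was taken after 15 days. The labels do not say that each array came from a different animal, so p-values measure the spread between these arrays. Values are log2 expression from GCRMA, which for Affymetrix probes corrects background, by default normalizes between arrays, and summarises probe sets. They were read back from a table whose decimal points had been lost. The median log2 value per array over all probe sets lay between 2.79 and 2.80 in the CoCl2 group and between 2.84 and 2.89 in the control group. The number of arrays limits the precision, with a median standard error of 0.21 for a log2 difference. The files do not pair probe sets with genes, so results are given for probe sets, and gene names appear only for control probe sets whose IDs carry them.

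The main comparison asked which transcripts differ in whole blood between CoCl2-treated and control mice. Of 22518 tested probe sets, 10163 (45.1%) differed at a Benjamini-Hochberg adjusted p under 0.05 in limma. In the CoCl2 group, 6442 were higher and 3721 lower, so 63.4% of the differences were rises. A change of at least 2-fold was found in 5586 probe sets, of which 3255 rose and 2331 fell. On this scale 884 probe sets fell at least 4-fold and 368 rose as much, but with arrays centred on the bacterial control RNAs bioB and bioC (described further on) 146 fell and 11327 rose at least 4-fold. That centring adds the shift of bioB and bioC to every probe set, also to those near the low end of the scale. Other added controls, bioD and cre, differed less between the groups, but lay at higher levels, cre near the top of the scale. Rises of at least 4-fold numbered 222 and falls 1003 after quantile normalization, and 265 and 1015 after median centring. At least 16-fold falls numbered 112, and rises of that size 0, the largest rise being 3.72 on the log2 scale. Where the CoCl2 mean lies near the low end of the scale, as in the largest falls named below, the size of a fall depends on that low end. Centred on the bacterial controls, 4 fell and 238 rose at least 16-fold, and the largest rise was 5.54. Without any overlap between the groups were 10255 tested probe sets (45.5%), where chance gives 2.86%. The median log2 difference over all tested probe sets was 0.19, and since the test is against 0, the counts include that shift. Median centring of the arrays moved the median difference to 0.05 and the share of rises to 51.9%. The medians used there were not those over all probe sets given above, which were lower in the CoCl2 group and would have raised the differences. The fold criterion mattered too, since 3085 probe sets passed limma's treat test against a 1.5-fold minimum.

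**Figure D1:**
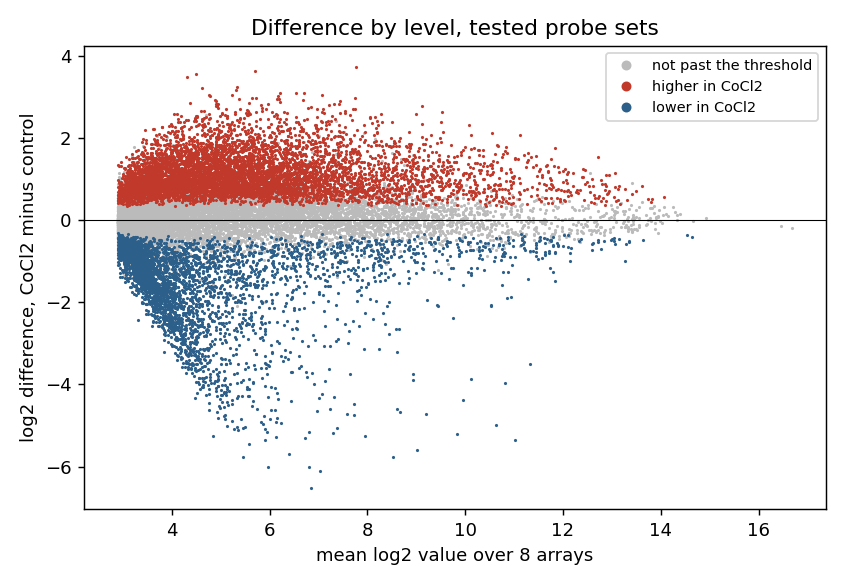
Log2 difference between CoCl2 and control arrays (vertical) against the mean log2 value over the 8 arrays (horizontal), 1 point per tested probe set, coloured by whether it was higher (6442), lower (3721) or not past the threshold. The deepest fall lies at -6.52 on the log2 scale, and the highest rise is 3.72.

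The balance of rises and falls by signal level is given on the restored scale. Among 9908 tested probe sets with a mean log2 value under 4, 1540 rose and 1819 fell. Among 6963 with a mean from 4 to 6, 2773 rose and 1218 fell, and 594 of the falls were at least 4-fold. From 6 to 8, 1358 of 3426 rose and 365 fell. From 8 to 10, 504 of 1397 rose and 180 fell. At 10 and above, 267 of 824 rose and 139 fell, and the median log2 difference there was 0.08. The balance depended on the scaling at every level. After quantile normalization, 1970 rose and 1426 fell from 4 to 6, 834 and 594 from 6 to 8, and 326 and 294 from 8 to 10. Centred on the bacterial controls, 3257 rose and 73 fell from 6 to 8. Under 4, 1745 rose and 1567 fell after quantile normalization, and 9077 rose and 34 fell when centred on the bacterial controls. At 10 and above, 205 rose and 215 fell after median centring.

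The largest rises among probe sets past the threshold with no overlap between groups were those of 1459873_x_at and 1418806_at. Probe set 1459873_x_at had a log2 value of 9.63 ± 0.34 (SD, n = 4) in the CoCl2 group and 5.90 ± 1.07 (SD, n = 4) in the control group. Its log2 difference was 3.72 (SE 0.47, limma adjusted p = 0.000482). Probe set 1418806_at stood at 7.51 ± 1.72 (SD, n = 4) with CoCl2 and 3.89 ± 0.33 (SD, n = 4) in controls, a log2 difference of 3.63 (SE 0.72, limma adjusted p = 0.00422). Its CoCl2 arrays spread from 5.88 to 9.09, and its control mean lay under 4, in the lowest range of tested levels. The largest falls were those of 1429993_s_at and 1442213_at. Probe set 1429993_s_at fell by 6.52 on the log2 scale (SE 0.47, limma adjusted p = 3.4e-05), from 10.11 ± 0.40 (SD, n = 4) in controls to 3.59 ± 1.05 (SD, n = 4) with CoCl2. Probe set 1442213_at fell by 6.11 (SE 0.40, limma adjusted p = 1.9e-05), from 10.09 ± 0.33 (SD, n = 4) to 3.98 ± 0.87 (SD, n = 4). With CoCl2, the means of both lay under 4, in that same range. Centred on the bacterial controls, the log2 differences were 5.54 for 1459873_x_at, 5.45 for 1418806_at, -4.70 for 1429993_s_at and -4.29 for 1442213_at.

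The control probe sets gave levels for a few named RNAs. The beta-actin probe sets (cytoskeletal actin) averaged 12.32 ± 0.09 (SD, n = 4) with CoCl2 and 11.67 ± 0.08 (SD, n = 4) in controls, a log2 difference of 0.65 (two-sided exact permutation p = 0.0286) that was 2.47 when arrays were centred on the bacterial controls described next. Those of Gapdh (a glycolytic enzyme) averaged 10.52 ± 0.04 (SD, n = 4) and 10.49 ± 0.12 (SD, n = 4), with a log2 difference of 0.03 and a two-sided exact permutation p of 0.743. That Gapdh difference was -0.14 after quantile normalization, -0.11 after median centring and 1.85 when centred on the bacterial controls. One B1 and 1 B2 probe set, which detect short interspersed repeats found in many mouse transcripts, averaged 11.39 ± 0.27 (SD, n = 4) with CoCl2 and 12.93 ± 0.25 (SD, n = 4) in controls. Their log2 difference was -1.55 (two-sided exact permutation p = 0.0286), and it was 0.27 when arrays were centred on the bacterial controls. Relative to the median of the tested probe sets it was -1.73 on both scales, as it must be, since centring moves all probe sets of an array alike. The B1 probe set alone differed by -2.22 and the B2 probe set by -0.87, and a second B2 probe set, not in that mean, by -1.18. The bacterial controls differed by -1.82, so when centred on them B1 alone stays lower with CoCl2 and both B2 probe sets are higher. The middle 18S ribosomal RNA probe set differed by -0.65 and that of the transferrin receptor, an iron uptake receptor, by -0.34 at a low level, 3.37 ± 0.06 (SD, n = 4) against 3.71 ± 0.15 (SD, n = 4) (exact permutation p = 0.0286 for each). Centred on the bacterial controls these differences turned to 1.17 and 1.48. The other 18S probe sets were higher with CoCl2, by 0.40 at the 3' end (exact permutation p = 0.114) and 0.43 at the 5' end (exact permutation p = 0.0857). The transferrin receptor's 3' probe set differed by -0.36 (exact permutation p = 0.143) and its 5' probe set by -0.07 (exact permutation p = 0.0286), at 2.51 with CoCl2 and 2.58 in controls. The p of 0.0286 is the smallest that 4 against 4 arrays can give, and over 74 controls and their summaries it came to 0.0587 after Benjamini-Hochberg adjustment, above 0.05.

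RNA quality was compared through 3' minus 5' differences, which grow as RNA breaks down. That of beta-actin was 1.69 ± 0.08 (SD, n = 4) with CoCl2 and 1.88 ± 0.10 (SD, n = 4) in controls (two-sided exact permutation p = 0.0571). For Gapdh it was 1.75 ± 0.19 (SD, n = 4) and 1.55 ± 0.12 (SD, n = 4), with an exact permutation p of 0.114. The 3' minus middle difference of beta-actin was 1.21 ± 0.06 (SD, n = 4) and 1.36 ± 0.05 (SD, n = 4) (exact permutation p = 0.0286, adjusted 0.0587), and that of Gapdh 1.60 ± 0.07 (SD, n = 4) and 1.67 ± 0.09 (SD, n = 4) (exact permutation p = 0.257). Bacterial RNAs added at hybridisation, which do not come from the mice, differed between the groups. The bioB and bioC probe sets averaged 11.34 ± 0.13 (SD, n = 4) on CoCl2 arrays and 13.16 ± 0.22 (SD, n = 4) on control arrays, a log2 difference of -1.82 (two-sided exact permutation p = 0.0286, adjusted 0.0587). The 4 bioD probe sets, at higher levels, differed by less, from -1.37 to -0.48 (exact permutation p = 0.0286 for each). The cre probe sets, near the top of the scale, lay between 15.61 and 16.13 on average in both groups. When arrays were centred on bioB and bioC, 20500 probe sets were higher and 518 lower in the CoCl2 group. The labels give no processing batch, and the ID numbers in the sample titles fall in separate ranges for the 2 groups, so batch and group cannot be told apart. The titles call the controls chamber controls, and the labels do not say whether they were housed as the treated mice were.

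**Figure D2:**
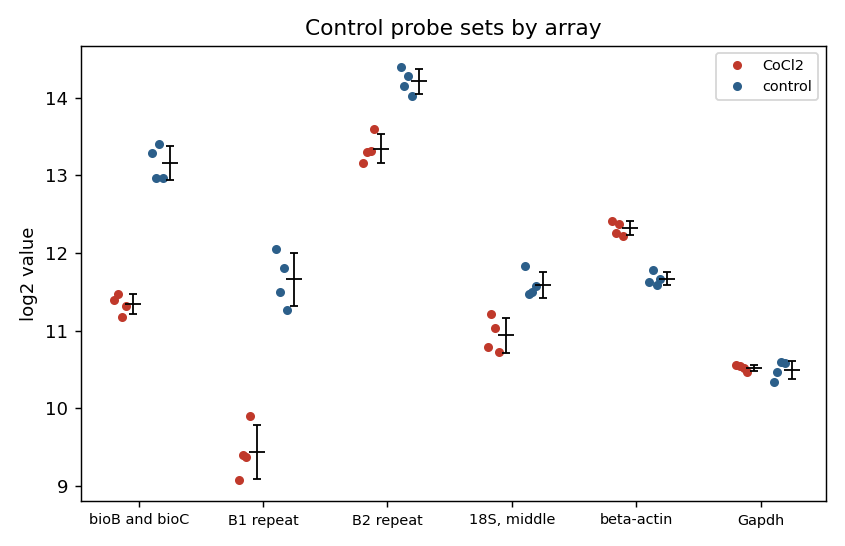
Log2 values of control probe sets (vertical) by array, with CoCl2 arrays in red and control arrays in blue, and the mean ± SD of each group as black bars. The bioB and bioC controls average 11.34 on CoCl2 arrays and 13.16 on control arrays, and beta-actin 12.32 and 11.67. B1, B2 and the middle 18S probe set are lower on CoCl2 arrays in the restored values. Centred on bioB and bioC, the B1 and B2 mean and the middle 18S are higher there, while B1 alone stays lower.

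Arrays of one group resembled each other more than those of the other. The Pearson correlation over tested probe sets averaged 0.969 within groups (0.951 to 0.982) and 0.872 between groups (0.833 to 0.907). The difference of 0.096 was the highest of the 35 splits of the arrays into 4 and 4 (one-sided exact permutation p = 0.0286, the smallest possible). Component 1 of a principal component analysis held 71.8% of the variance and separated the groups, with scores of 70.86 to 81.95 for CoCl2 arrays and -100.83 to -49.34 for control arrays. Component 2 held 8.07%.

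**Figure D3:**
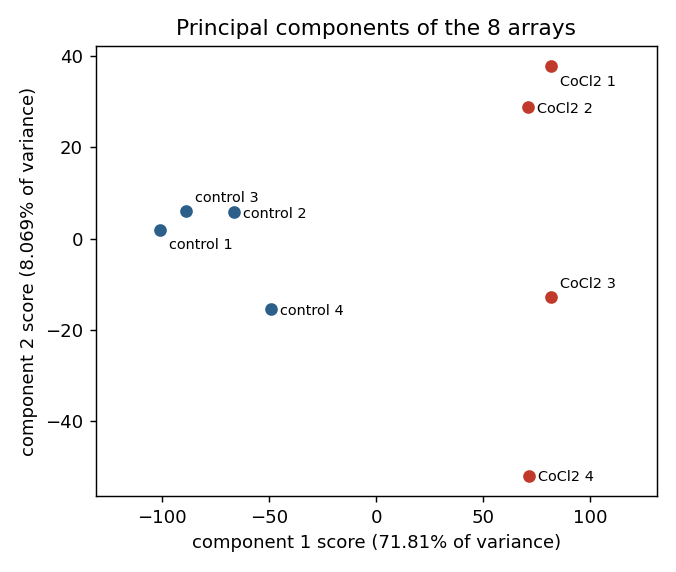
Scores of the 8 arrays on principal components 1 (horizontal) and 2 (vertical) over the tested probe sets, with CoCl2 arrays in red and control arrays in blue. The groups separate on component 1 (71.8% of the variance), and on component 2 (8.07%) CoCl2 replicate 1 stands at 37.79 and CoCl2 replicate 4 at -52.03.

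The authors' deposited table of a SAM comparison, which ranks probe sets by a moderated difference with a permutation-based q-value, lists 24878 probe sets. In the authors' deposited table, 17184 have a q-value under 5%, of which 11837 have a positive and 5347 a negative score. Of 20366 probe sets tested in both, 9823 passed in the limma fit and in the authors' deposited table, all in the same direction. Another 125 passed in the limma fit alone and 5065 in the authors' deposited table alone. Across the 24845 probe sets of the authors' deposited table that are not AFFX controls, its log2 differences and those from the restored values correlated at r = 0.952. Their median absolute gap was 0.19, and 93.2% had the same sign. Probe sets are not independent replicates.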

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

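The tests of ambiguous cells over all calls, of separate hybridisation, of repeat-bearing RNA and of normalization behind the bacterial controls, the mean over 3 repeat probe sets, and the counts of splits for rises, falls and 2-fold changes, were chosen after the results were seen. Of 38 groups of 4 values examined, 2 held an array far from the other ones, and chance gives about 1 in 20. The Gapdh 3' minus 5' difference of control replicate 3 was 1.38, while the other control arrays lay between 1.59 and 1.62. On component 3, which held 7.45% of the variance, control replicate 4 stood at -61.62 and the other control arrays between 10.38 and 21.54.

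Of the tested probe sets, 45.1% differed between the groups. In limma 1 of 35 splits, the real one, gave 10163 probe sets and the highest other split 0 (3744 at an unadjusted p under 0.05, against 12202 in the real split). Every other split mixes the groups, whose difference then widens the spread, so a low count there was likely in advance. That the real split ranked first argues against chance assignment of arrays only at the limit of 1 in 35, and does not exclude it. The rises, falls and 2-fold changes are parts of the 10163, so their 1 of 35, with 0 as the highest other, adds nothing. Ambiguous decimals are argued against as the source, since 2.09% of the probe sets past the threshold hold an ambiguous cell. After quantile normalization 9165 probe sets passed, 8314 of them as in the main fit. GCRMA by default already normalizes between arrays, and the array medians over all probe sets lay close together (2.79 to 2.89). A count near the main one was therefore likely in advance and cannot decide whether unevenness between arrays contributed. Centring on bioB and bioC gave 21018, so an effect of scaling stays open. Separate hybridisation of the groups, with bioB and bioC differing by -1.82, cannot be told apart from the treatment, because no batch is given. An effect of CoCl2 stays open and was not tested apart from it.

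The 884 probe sets that fell at least 4-fold moved with the B1 and B2 repeat controls within groups. Over the 8 arrays, their mean deviation from the group mean correlated with that of the repeat controls at r = 0.897 (exact permutation p = 0.00521 over 576 arrangements, adjusted 0.013 over 3 relations) and rho = 0.905 (exact permutation p = 0.0104), and r was 0.804 without the 2 arrays farthest from the median; with a second B2 probe set in the mean (3 probe sets), r was 0.918 (exact permutation p = 0.00347; rho = 0.952, p = 0.00347; 0.904 without 2 arrays). The 368 probe sets that rose as much gave r = -0.104 (exact permutation p = 0.828, adjusted 0.828; rho = -0.262, p = 0.55; -0.528 without those arrays), and 5806 brighter ones not past the threshold r = -0.891 (exact permutation p = 0.00868, adjusted 0.013; rho = -0.881, p = 0.0104; -0.583 without them). Ambiguous decimals are argued against, since 1.7% of the falling probe sets hold an ambiguous cell. More RNA with repeats or introns in the control preparations is a candidate explanation, and whether it would come from preparation or from CoCl2 was not tested. The 5806 brighter probe sets not past the threshold (mean log2 of at least 4) followed the repeat controls about as closely over all 8 arrays, in the opposite direction. Without the 2 farthest arrays they followed less closely (r = -0.583 against 0.804). The relation is therefore not particular to the falling ones. Which probe sets detect repeats or introns is not known here, so the relation cannot decide for this explanation.

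The bacterial controls bioB and bioC were lower on CoCl2 arrays by more than the arrays' spread. GCRMA by default includes a normalization that evens out the signal between arrays, and such normalization stays open as a cause. It would hold the mouse median near 0 (0.1855 here over all tested probe sets) and move added controls off by the shift it removed. Centred on bioB and bioC, that median was 2.00. Separate hybridisation may account for the difference too, but 0 batches in the labels or files hold both groups, so it cannot be told apart from the treatment.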

How the results depend on the processing

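Centring on bioB and bioC, setting ambiguous cells to missing and testing the authors' probe sets were chosen after seeing the data. The 4 named probe sets kept their direction and stayed past the threshold in all 18 alternatives each (highest adjusted p 0.025, limma), though centring on bioB and bioC moved each difference up by the controls' shift. They were chosen as the largest differences without overlap, so this was likely in advance and does not speak for other probe sets. Without 1 array at a time, the probe sets past the threshold numbered 8012 to 10297, those higher 5058 to 6424, those lower 2901 to 3873 and those changed 2-fold 4824 to 5989. These 4 counts stayed within 1.5 times in the other alternatives apart from those that follow. The authors' table gave 17184 past its threshold and 11837 higher; the cause was not tested. limma's treat test, stricter by construction, gave 3085. Centring on bioB and bioC adds the controls' difference to every probe set. It gave 21018 past the threshold, 20500 higher, 518 lower and 19998 changed 2-fold, with a median log2 difference of 2.00. The mean B1 and B2 difference turned to 0.27 (B1 alone stayed lower), 18S to 1.17 and the transferrin receptor to 1.48. With that centring, beta-actin stood at 2.47 and Gapdh at 1.85. Median centring gave beta-actin 0.51, Gapdh -0.11 and the transferrin receptor -0.48. Quantile normalization gave Gapdh -0.14, its 3' minus 5' difference 0.41 and its 3' minus middle difference 0.13. Leaving out arrays gave Gapdh -0.024 to 0.058, with 0.028 over all arrays. The correlation gap was 0.060 with no filter, 0.131 with a stricter filter and 0.087 to 0.110 without 1 array. For these the cause was not tested.

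The replicate numbers did not pair the arrays, since deviations of same-numbered arrays correlated between -0.04 and 0.02. With the number as a block, 9216 probe sets passed, 8890 of them as in the fit without it. Ambiguous cells set to missing left 10151, of which 10133 were shared. Signal near the low end limits 9908 of the tested probe sets, with means under 4.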

Other observations

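The association below was tested after it was seen. Falls were unevenly spread over the suffix classes of the IDs. Of 17006 tested probe sets with the plain suffix _at, 12.3% fell at least 2-fold, against 3.03% of 2636 with _a_at, 4.72% of 1377 with _s_at and 6.27% of 1499 with _x_at (Fisher's exact test of _at against the rest, p = 1.1e-74, adjusted 4.4e-74 over 4 classes; probe sets are not independent). At least 2-fold rises were found in 2205 of the 17006 _at, 594 of the 2636 _a_at, 259 of the 1377 _s_at and 197 of the 1499 _x_at probe sets. These shares and counts are on the restored scale. Centred on bioB and bioC, 2.02% of _at, 0.379% of _a_at, 0.508% of _s_at and 0.934% of _x_at probe sets fell at least 2-fold (Fisher's exact test of _at against the rest, p = 5.9e-16). With that centring, 14427 _at, 2528 _a_at, 1285 _s_at and 1384 _x_at probe sets rose at least 2-fold.

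Arrays differed in how many tested probe sets set them far from the other arrays of their group. Control replicate 4 was far in 3.88% and CoCl2 replicate 4 in 3.13% of probe sets, and CoCl2 replicate 3 in 1.02%. By chance about 1 in 20 groups of 4 values hold such a far array, so each array would be far in some probe sets. On component 2 the CoCl2 arrays stood at 37.79, 28.79, -12.87 and -52.03. The poly-A control probe sets (dap, lys, phe, thr and trp) stood between 2.21 and 2.64 on average in both groups.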
